A study of Homo sapiens with 12 samples.

How the data were processed

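RNA sequencing of 12 libraries of the human DLBCL lines VAL and OCI-LY3 was re-analysed. Each line had 2 libraries untreated (0 h), 2 after 3 h and 2 after 6 h of 300 nM AZ5576. Per the labels' protocols poly(A)+ RNA was taken through an unstranded library kit and sequenced as single reads. Per the labels the VAL libraries were run on one lane and the OCI-LY3 libraries on another, and the VAL libraries numbered 1 are marked as resubmitted. Per the submitters' processing notes reads were assigned to genes of GRCh38 and normalized with DESeq2; its version, the aligner and the counting tool are not given in the sources used here.

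A table of raw values deposited by the authors holds a read count per gene and library, for 58233 genes, of which 35090 had a count. A second deposited table holds normalized expression that is already in log2. Of its values 99.997% lay within 0.01 of DESeq2's regularized log of the deposited counts, computed with knowledge of the groups. Gene names, spans, strands and types were read from GENCODE release 29, where 57895 identifiers of the table were found; the annotation the authors used need not be the same. Depth ranged from 23175082 to 39715536 counts per library. Intervals and floors cover counting error only, as reads carry no molecular identifiers.

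Genes with enough counts by edgeR's default filter (filterByExpr) for the 6 groups were tested, 16374 in all. Counts were scaled by TMM and fitted in one model with edgeR's quasi-likelihood test, 6 residual degrees of freedom and Benjamini-Hochberg adjustment within each comparison. An adjusted p under 0.05 was the threshold, and genes changed at least 2-fold were counted beside it, which is the fold the series text gives. The comparisons were 3 h and 6 h with 0 h and 6 h with 3 h in each line, OCI-LY3 with VAL at 0 h, and the difference between lines of the change at 3 h and at 6 h. Standard errors of log2 changes are from the fitted model. Replicate numbers do not pair libraries by any statement in the labels, so no block was used. All tests are two-sided. With 2 libraries per group no test by regrouping samples could pass, and no outlier test applies. Folds against a group without counts are given as least folds over a floor of 3 counts for the group.

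Gene lists, 37 in number, were fixed before the data were examined, as were the comparisons, the threshold, the alternatives and the rule for naming genes. Of them 35 had at least 5 tested members and were tested with limma's camera at a preset correlation of 0.01, adjusted over lists within a comparison. The lists of epithelial and stromal markers and of erythroid markers had 2 and 0 tested members and were not tested. Each list was also tested with a correlation estimated from the libraries, with fry, and with a replicate block. Members were counted as higher, lower or not passing by the adjustment over all genes, and again adjusted over the list alone.

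Genes named in the text are, first, 20 core genes of CDK9 biology and B-cell survival. Second, in each comparison with 0 h, the 6 highest and 6 lowest named protein-coding genes are named among those that passed, had a mean of at least 5 CPM over the line's libraries, and had both treated libraries on the same side of both controls. In the other comparisons 5 higher and 5 lower are named. Last, of each list described by its members, up to 4 with the smallest adjusted p are named, with members that passed against the majority. Lists given by counts alone name no member. Some genes that these rules pick are not reported here; they stay in the tests and in the counts of genes. Genes named for the return after 3 h, for the trace between lines, and MPO, CD14 and VIM, were chosen after their values were seen.

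Alternatives were DESeq2's size factors, no composition factor, upper-quartile factors, scaling to mitochondrially encoded or to ribosomal protein mRNAs, no low-count filter, a minimum mean of 5 CPM, DESeq2's Wald test, limma-voom, limma on the deposited log2 table, each line fitted alone, a replicate block, a 2-fold minimum, and leaving out each library in turn. Added after the data were seen were limma-voom with one weight per group, leaving out the treated VAL libraries numbered 1 or those numbered 2, and leaving out genes over 10 times higher in the other line. Correlations within a line were set against 100 simulated draws of unchanged groups that share the 0 h libraries. Neighbours of rising genes were sought within 10 kb among genes of at least 20 CPM, and the limits of 2 CPM and 4-fold for risers were the first tried. The return of genes was tested against gene span with a permutation test.

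Simulation tested the steps with few changes, not scaling shifts or unequal spread. Of 100 genes planted at 2-fold in each comparison with 0 h, 72% to 81% were found, and 89% to 97% of 100 at 4-fold. False calls were 8 to 15. A planted list was found in all 4 comparisons, and at most 1 of 36 other lists was called.

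Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9. No library was left out of the comparisons. Reads were not aligned again, and splicing and variants were not analysed here. Genes of the sex chromosomes that would show a donor's sex were not reported.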

Results

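Poly(A)+ RNA was sequenced from VAL and OCI-LY3, established cell lines of diffuse large B-cell lymphoma (DLBCL), an aggressive cancer of mature B cells. Cells were collected untreated (0 h) or after 3 h or 6 h with 300 nM AZ5576, a selective inhibitor of CDK9. CDK9 is the kinase of P-TEFb, which releases paused RNA polymerase II into elongation. Each of the 6 groups of line and time held 2 libraries, 12 in all. Total counts in VAL were 34134616 and 31561576 at 0 h, 30393475 and 27129753 at 3 h, and 28303815 and 25321061 at 6 h. In OCI-LY3 they were 36338085 and 39715536 at 0 h, 28865842 and 28552461 at 3 h, and 23175082 and 26305925 at 6 h. Values after ± are standard errors for log2 changes and standard deviations (SD) of 2 libraries for counts scaled to library size (CPM). The adjusted p-values measure only the spread between these libraries, since the labels do not say that replicates were separate cultures. Time-0 cells are the only controls in the labels, while the series text speaks of vehicle, so time in culture and vehicle are part of every change with treatment.

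Mitochondrially encoded and ribosomal protein mRNAs took up more of the treated libraries. In VAL the mRNAs encoded by the mitochondrial genome, which another polymerase transcribes, held 1.85 ± 0.146% of counts at 0 h, 3.92 ± 1.07% at 3 h and 6.03 ± 1.24% at 6 h. In OCI-LY3 they held 2.31 ± 0.087%, 4.51 ± 1.04% and 5.26 ± 0.17%. Messages for ribosomal proteins went from 11.4 ± 0.0424% to 16.3 ± 2.17% and 21 ± 2.46% in VAL, and from 9.16 ± 0.211% to 12.9 ± 0.919% and 15.5 ± 0.127% in OCI-LY3. RNA-seq without added standards shows each gene relative to the rest, so a loss of most short-lived RNA would appear as a gain of stable RNA. With the default scaling the median change of all 16374 tested genes was 0.14 and 0.08 in VAL at 3 h and 6 h, and 0.00 and -0.01 in OCI-LY3. Scaled so that mitochondrially encoded mRNAs stayed level, these medians became -1.23, -2.03, -1.07 and -1.50. Whether a modest rise is a gain in amount is not known from these data. Rises named below for a comparison that turned negative with such scaling are given with their values in the part on processing choices.

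**Figure D1:**
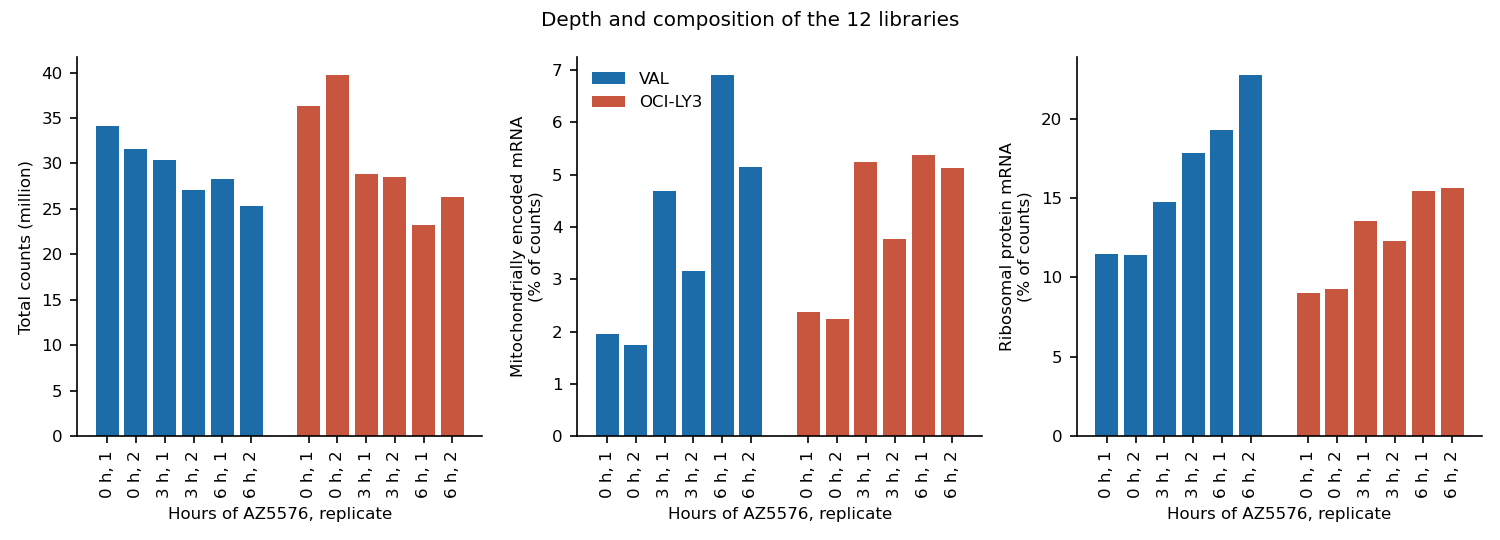
Bars give, for each library by hours and replicate number, total counts (in units of 1e+06), the percent of counts from mitochondrially encoded mRNAs and the percent from ribosomal protein mRNAs, with VAL in blue and OCI-LY3 in red. Mitochondrially encoded mRNAs held 1.85% of VAL counts at 0 h and 6.03% at 6 h.

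The first comparison asked which transcripts VAL lost within 3 h of CDK9 inhibition. Short-lived regulators fell: the survival factor MCL1, the B-cell transcription factor IRF4, the AP-1 member JUNB, the NF-kB inhibitor NFKBIA and the kinase PIM1. MYC, often described as sensitive to CDK9 inhibition, did not pass the test with the default scaling. Of 16374 genes, 4840 rose, 4112 fell and 7422 did not pass; at least 2-fold changes numbered 1943 and 2608. MCL1 (ENSG00000143384, chromosome 1, 150574551 to 150579738, GRCh38) changed by -1.88 ± 0.16, adjusted p = 4.03e-06, from 237 ± 1.6 CPM to 64.2 ± 15.9 CPM, which is 3.69-fold lower. JUNB changed by -3.12 ± 0.139, adjusted p = 9e-08, NFKBIA by -3.58 ± 0.199, adjusted p = 2.62e-07, IRF4 by -3.16 ± 0.192, adjusted p = 4.06e-07 and PIM1 by -1.61 ± 0.0971, adjusted p = 3.99e-07. MYC stood at 134 ± 8.19 CPM against 136 ± 1.59 CPM (adjusted p = 0.866). The immediate-early genes IER2 (-2.63 ± 0.137) and EGR1 (-1.34 ± 0.239) fell, and FOS did not pass (-1.28 ± 0.728, adjusted p = 0.158). Of the other anti-apoptotic genes BCL2L1 (-0.86 ± 0.111, adjusted p = 8.58e-05) and BCL2A1 (-0.65 ± 0.152, adjusted p = 0.00408) had smaller falls. BCL2 varied widely between libraries, at 350.1 ± 226 CPM against 430 ± 11.1 CPM (adjusted p = 0.557). CDK9 itself (-1.04 ± 0.105, adjusted p = 1.37e-05), its cyclin CCNT1 (-1.45 ± 0.167, adjusted p = 3.7e-05) and its inhibitor HEXIM1 (-0.69 ± 0.14, adjusted p = 0.00171) fell. POLR2A rose slightly (0.49 ± 0.162, adjusted p = 0.0241), a sign that turned with scaling to mitochondrial or ribosomal protein mRNAs. BCL6 (0.14 ± 0.101, adjusted p = 0.258) and CCND2 (1.15 ± 0.794, adjusted p = 0.243) did not pass, and the p53 target CDKN1A fell (-1.27 ± 0.17, adjusted p = 0.000106).

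Among genes of at least 5 CPM the largest losses in VAL at 3 h included DDIT3 (-5.26 ± 0.268, adjusted p = 1.74e-07), DNAJB1 (-4.83 ± 0.162, adjusted p = 3.25e-08) and the transporter MFSD2A (-4.91 ± 0.259). The B-cell regulator ID3 (-4.95 ± 0.404), CCDC71 (-4.86 ± 0.291) and NRBF2 (-4.80 ± 0.25) completed the 6. The largest gains were in genes silent or nearly so at the start, such as growth hormone GH1 (ENSG00000259384, chromosome 17, 63917200 to 63918838), which went to 32.4 ± 2.83 CPM against 0.737 ± 0.0688 CPM (5.45 ± 0.258, adjusted p = 1.16e-07). GH1 has near-identical paralogs, so its reads are not assigned to it with certainty. The others were TEX29 (4.68 ± 0.305), GALNT11 (4.42 ± 0.251), the hyaluronan synthase HAS3 (3.76 ± 0.194), PHLDA1 (3.62 ± 0.35) and GABRR2 (3.68 ± 0.636), which stood at 5.98 ± 4.85 CPM. The libraries were made without strand information, so counts in such genes can come from overlapping or neighbouring transcription.

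Immediate-early genes, induced within minutes by growth signals, fell as a group in VAL at 3 h (1 rose, 20 fell and 7 did not pass, or 1 and 21 adjusted over the list alone). They included DUSP2 (-4.05 ± 0.167, adjusted p = 7.18e-08), IER5 (-2.98 ± 0.133) and ZFP36 (-2.92 ± 0.147), while CYR61 (3.00 ± 0.562) rose. This was the only list that kept its call with an estimated correlation (adjusted p = 4.01e-13, or p = 0.00473 with an estimated correlation). NF-kB targets fell too (6 rose, 22 fell and 11 did not pass, or 7 and 22 adjusted over the list alone; adjusted p = 6.42e-07, or p = 0.0911 with an estimated correlation), led by BCL3 (-2.64 ± 0.114), IRF1 (-3.94 ± 0.172), ICAM1 (-3.69 ± 0.175) and NFKBIE (-3.52 ± 0.17). Against them CD74, CCL22, CCL17, EBI3, STAT5A and CCL5 rose. In the STAT3 and IL10 axis 3 rose, 9 fell and 4 did not pass, or 4 and 9 adjusted over the list alone (adjusted p = 1.41e-05, or p = 0.0911 with an estimated correlation); SOCS1 (-4.83 ± 0.208) and IL10RA (-3.45 ± 0.145) were lost, and JAK1 and STAT3 were among those that rose. Of the p53 targets 1 rose, 21 fell and 6 did not pass (adjusted p = 1.53e-07, or p = 0.198 with an estimated correlation), with GADD45A (-3.62 ± 0.179) and FAS (-1.64 ± 0.109) lower and FDXR higher. Pro-apoptotic BCL2 genes, BAK1 (-1.90 ± 0.146) and BCL2L11 (-1.40 ± 0.142) among them, fell as well, as 0 rose, 6 fell and 5 did not pass (adjusted p = 0.0484, or p = 0.446 with an estimated correlation). Of 5 anti-apoptotic BCL2 genes 3 fell, and that list did not pass (adjusted p = 0.115).

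Genes of P-TEFb and elongation fell in VAL at 3 h (4 rose, 14 fell and 20 did not pass; adjusted p = 0.0096, or p = 0.135 with an estimated correlation). Among them were BRD2 (-2.19 ± 0.0932), MEPCE (-2.48 ± 0.154) and CDK7 (-2.00 ± 0.193), while MNAT1, NELFCD, SUPT6H and SUPT5H rose. KRAB zinc-finger genes, repressors with short-lived messages, fell in bulk (4 rose, 41 fell and 16 did not pass, or 4 and 44 adjusted over the list alone; adjusted p = 1.08e-10, or p = 0.142 with an estimated correlation). ZNF263 (-2.59 ± 0.118) and ZNF184 (-3.86 ± 0.2) were lowest by adjusted p, and ZNF37A, ZNF66, ZNF83 and ZNF69 rose. Short intronless genes also fell (1 rose, 28 fell and 1 did not pass; adjusted p = 2.85e-13, or p = 0.0604 with an estimated correlation), among them ARF6 (-3.36 ± 0.187) and ZNF830 (-2.59 ± 0.141), against GPR3 (2.52 ± 0.524). The medians of these last 3 lists stayed negative under every scaling. Ribosomal protein genes rose (73 rose, 0 fell and 2 did not pass; adjusted p = 8.94e-12, or p = 0.595 with an estimated correlation; RPL28 0.97 ± 0.116), but their median turned to -0.58 with mitochondrial scaling. Nuclear respiratory-chain genes rose likewise (35 rose, 0 fell and 5 did not pass; adjusted p = 3.89e-05, or p = 0.628 with an estimated correlation; SDHC 0.83 ± 0.101), with a median of -0.78 under that scaling. All 13 mitochondrially encoded mRNAs rose (adjusted p = 3.72e-06, or p = 0.418 with an estimated correlation; MT-ND2 1.41 ± 0.165), and still did at a median of 0.53 when scaled to ribosomal proteins. Leaving out VAL 0 h replicate 1 or 2 took the genes called higher to 2244 or 2279. The replicates of treated VAL also differed more than any other pair, with a chi-square per degree of freedom of 63.7 at 3 h and 1.66 at 0 h, and the fit pools this spread over groups.

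The next comparison asked what VAL looked like after 6 h. MCL1 had partly returned, JUNB, IRF4 and NFKBIA remained low, and MYC, BCL6 and CDKN1A stood above their starting levels. At 6 h 5564 genes rose, 5265 fell and 5545 did not pass, with at least 2-fold changes in 3505 and 3610. MCL1 changed by -0.95 ± 0.156, adjusted p = 0.000273, at 122 ± 9.91 CPM. JUNB (-2.39 ± 0.134, adjusted p = 1.28e-07), IER2 (-2.05 ± 0.134, adjusted p = 3.32e-07), IRF4 (-2.34 ± 0.183, adjusted p = 1.09e-06) and NFKBIA (-2.30 ± 0.185, adjusted p = 1.32e-06) were still lower. CDK9 (-1.05 ± 0.105, adjusted p = 6.6e-06), CCNT1 (-0.54 ± 0.163, adjusted p = 0.0124), HEXIM1 (-0.50 ± 0.14, adjusted p = 0.00858), PIM1 (-0.51 ± 0.0946, adjusted p = 0.000671) and BCL2L1 (-0.60 ± 0.111, adjusted p = 0.000612) were modestly lower. MYC rose (0.67 ± 0.091, adjusted p = 7.18e-05) to 216 ± 6.15 CPM, BCL6 rose (1.12 ± 0.102, adjusted p = 3.36e-06), and so did CDKN1A (1.03 ± 0.167, adjusted p = 0.000263), but all 3 signs turned with mitochondrial or ribosomal protein scaling. BCL2 (0.36), BCL2A1 (-0.03), FOS (0.87), EGR1 (-0.40), POLR2A (0.33) and CCND2 (1.74) did not pass. The largest losses were RPUSD2 (-5.98 ± 0.25, adjusted p = 4.75e-08), DNAJB1 (-5.15 ± 0.168), MFSD2A (-5.13 ± 0.272), ZNF200 (-5.07 ± 0.219), VPS18 (-4.91 ± 0.183) and the serum-responsive kinase SGK1 (-4.89 ± 0.27). The largest gains were GH1 (6.75 ± 0.265, adjusted p = 4.45e-08), PHLDA1 (5.83 ± 0.355), TEX29 (5.54 ± 0.303), CPM (4.76 ± 0.337), C1orf162 (4.72 ± 0.367) and HAS3 (4.66 ± 0.192).

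Mitotic genes fell at 6 h in VAL (1 rose, 26 fell and 5 did not pass, or 2 and 26 adjusted over the list alone; adjusted p = 2.9e-08, or p = 0.102 with an estimated correlation). AURKA (-3.80 ± 0.159, adjusted p = 4.75e-08), TTK (-4.62 ± 0.229), PLK4 (-2.84 ± 0.151) and CCNA2 (-2.17 ± 0.122) fell, and only PRC1 (0.64 ± 0.0893) rose. Nucleolar MYC targets, which build ribosomes, fell (2 rose, 25 fell and 7 did not pass; adjusted p = 1.02e-05, or p = 0.461 with an estimated correlation). Among them were POLR1B (-3.06 ± 0.134) and GRWD1 (-4.02 ± 0.21), against FBL and NPM1. Immediate-early genes were less reduced than at 3 h (2 rose, 15 fell and 11 did not pass; adjusted p = 0.00102, or p = 0.102 with an estimated correlation), with KLF6 (1.49 ± 0.391) and CYR61 (3.44 ± 0.543) higher. Of the P-TEFb and elongation genes 4 rose, 23 fell and 11 did not pass (adjusted p = 0.00202, or p = 0.102 with an estimated correlation), and of NF-kB targets 7 rose, 22 fell and 10 did not pass (adjusted p = 0.0011, or p = 0.184 with an estimated correlation). Replication-dependent histones, whose messages normally lack a poly(A) tail, rose (24 rose, 0 fell and 10 did not pass, or 25 and 0 adjusted over the list alone; adjusted p = 0.00353, or p = 0.548 with an estimated correlation), led by HIST1H3H (3.05 ± 0.306), though their median was -0.90 with mitochondrial scaling. Among pro-apoptotic genes BAK1 (-2.24 ± 0.151) and BMF (-2.43 ± 0.181) fell while the p53 target BBC3 (1.88 ± 0.224, adjusted p = 2.52e-05) rose, and the list did not pass (adjusted p = 0.238). Ribosomal protein genes rose further (73 rose, 0 fell and 2 did not pass; adjusted p = 6.65e-18, or p = 0.461 with an estimated correlation), again with a negative median of -0.84 under mitochondrial scaling. The treated replicates of VAL were again far apart, at a chi-square per degree of freedom of 51.9.

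**Figure D2:**
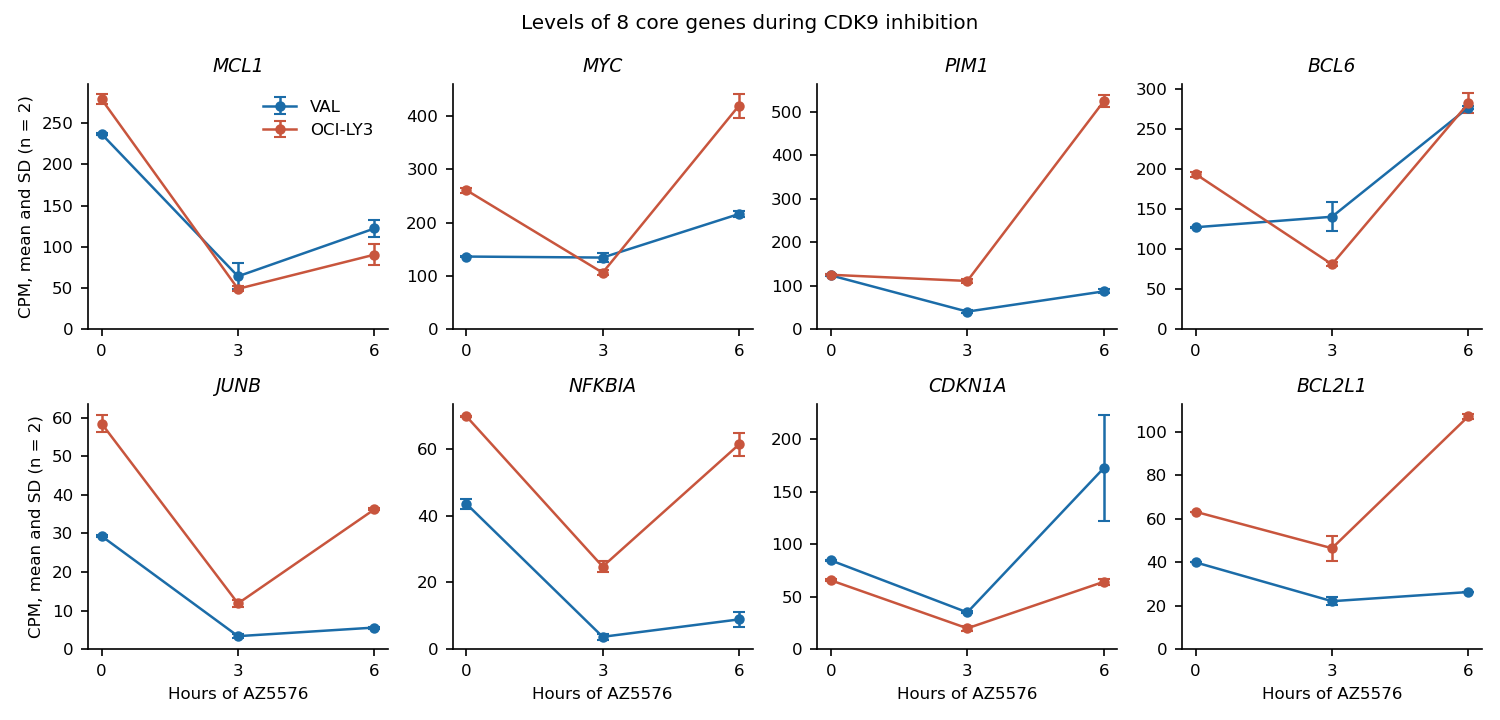
Mean CPM (y axis) ± SD of 2 libraries at 0, 3 and 6 h of AZ5576 (x axis) for MCL1, MYC, PIM1, BCL6, JUNB, NFKBIA, CDKN1A and BCL2L1, with VAL in blue and OCI-LY3 in red. MCL1 dipped at 3 h in both lines, to 64.2 CPM in VAL and 49 CPM in OCI-LY3, and PIM1 reached 524 CPM in OCI-LY3 at 6 h.

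The same question was asked at 3 h in OCI-LY3. MCL1, JUNB and IRF4 fell, and here MYC and the germinal-centre repressor BCL6 fell as well. PIM1, lost in VAL, did not pass. Of 16374 genes 2917 rose, 3983 fell and 9474 did not pass, and 1088 and 2326 changed at least 2-fold. MCL1 changed by -2.51 ± 0.164, adjusted p = 9.19e-07, from 279 ± 6 CPM to 49 ± 3.09 CPM, or 5.69-fold lower. MYC (ENSG00000136997, chromosome 8, 127735434 to 127741434) changed by -1.30 ± 0.0921, adjusted p = 1.47e-06, from 261 ± 4.61 CPM to 106 ± 4.3 CPM. BCL6 changed by -1.26 ± 0.103, adjusted p = 3.77e-06, JUNB by -2.30 ± 0.127, adjusted p = 3.98e-07, IER2 by -1.64 ± 0.13, adjusted p = 3.06e-06 and EGR1 by -1.23 ± 0.265, adjusted p = 0.00349. IRF4 (-1.81 ± 0.243, adjusted p = 0.00015), NFKBIA (-1.50 ± 0.173, adjusted p = 5.11e-05) and CDKN1A (-1.73 ± 0.174, adjusted p = 1.78e-05) also fell. Smaller losses were seen in BCL2L1 (-0.45 ± 0.109, adjusted p = 0.00722) and BCL2A1 (-0.41 ± 0.143, adjusted p = 0.0384). CDK9 (-0.97 ± 0.105, adjusted p = 3.08e-05), CCNT1 (-1.44 ± 0.167, adjusted p = 5.29e-05) and HEXIM1 (-0.91 ± 0.142, adjusted p = 0.000436) fell too. PIM1 (-0.17), BCL2 (-0.68), FOS (-1.15), POLR2A (0.02) and CCND2 (-0.32) did not pass. The largest losses were TIPARP (-4.75 ± 0.189, adjusted p = 1.67e-07), C15orf39 (-4.26 ± 0.118), TRIB1 (-4.18 ± 0.157), SGK1 (-4.06 ± 0.217), ID3 (-4.02 ± 0.399) and the interferon regulator IRF1 (-3.94 ± 0.169). The largest gains were GH1 (6.47 ± 0.354, adjusted p = 3.85e-07), the lipid carrier APOE (5.64 ± 0.324), PRR18 (4.77 ± 0.42), C1orf162 (4.26 ± 0.393), GAB2 (3.90 ± 0.203) and PHLDA1 (3.75 ± 0.367). The gene before GH1 on its strand, CD79B, is a highly expressed B-cell receptor subunit at 604 CPM in untreated OCI-LY3 and ends 9902 bp away.

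Immediate-early genes were again the only list called with an estimated correlation in OCI-LY3 at 3 h (1 rose, 18 fell and 9 did not pass, or 1 and 19 adjusted over the list alone; adjusted p = 3.59e-10, or p = 0.0476 with an estimated correlation). DUSP2 (-3.49 ± 0.164, adjusted p = 2.08e-07) and IER5 (-2.09 ± 0.129) fell and CYR61 (2.59 ± 0.496) rose. NF-kB targets fell (5 rose, 25 fell and 9 did not pass; adjusted p = 1.82e-07, or p = 0.0624 with an estimated correlation), MAP3K8 (-2.33 ± 0.119), NFKBIE (-2.91 ± 0.161) and PTGER4 (-2.90 ± 0.184) among them. CD74, CCL22, CCL17, EBI3 and CCL5 rose, as they did in VAL. Of the STAT3 and IL10 axis 0 rose, 8 fell and 8 did not pass (adjusted p = 1.73e-06, or p = 0.0969 with an estimated correlation), with IL10RA (-3.21 ± 0.148) and SOCS1 (-3.43 ± 0.16) lowest. Of the p53 targets 1 rose, 19 fell and 8 did not pass, or 1 and 20 adjusted over the list alone (adjusted p = 1.16e-07, or p = 0.212 with an estimated correlation), including GADD45A (-3.38 ± 0.193) and PLK3 (-3.61 ± 0.222), against FDXR. P-TEFb and elongation genes fell (2 rose, 20 fell and 16 did not pass; adjusted p = 0.00395, or p = 0.0923 with an estimated correlation), with BRD2 (-2.13 ± 0.0932) and MEPCE (-2.76 ± 0.157) lower and NELFCD and SUPT5H higher. KRAB zinc fingers (0 rose, 44 fell and 17 did not pass, or 1 and 46 adjusted over the list alone; adjusted p = 1.38e-14, or p = 0.0969 with an estimated correlation) and short intronless genes (0 rose, 24 fell and 6 did not pass; adjusted p = 1.8e-14, or p = 0.0601 with an estimated correlation) fell. Their lowest by adjusted p were ZNF263 (-2.28 ± 0.113), ZNF14 (-4.02 ± 0.225), GPR18 (-3.00 ± 0.161) and ARF6 (-3.35 ± 0.189). Among pro-apoptotic genes PMAIP1 (-1.94 ± 0.194) and BBC3 (-2.69 ± 0.279) fell, and the list did not pass (adjusted p = 0.0906). Ribosomal protein (73 rose, 0 fell and 2 did not pass; adjusted p = 3e-13, or p = 0.494 with an estimated correlation) and nuclear respiratory-chain genes (36 rose, 0 fell and 4 did not pass, or 39 and 0 adjusted over the list alone; adjusted p = 5.19e-08, or p = 0.494 with an estimated correlation) rose, with medians of -0.45 and -0.49 under mitochondrial scaling. The number of rises was 4520 with the OCI-LY3 libraries alone, on 14100 genes, and 1491, 1492 or 1620 without OCI-LY3 0 h replicate 1, 3 h replicate 1 or 0 h replicate 2.

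At 6 h OCI-LY3 had moved past its starting point for several of the same regulators. PIM1 was the clearest, and MYC, BCL6 and BCL2L1 also stood above 0 h. MCL1 remained low. In this comparison 4606 genes rose, 5469 fell and 6299 did not pass, and 2511 and 3573 changed at least 2-fold. MCL1 changed by -1.62 ± 0.159, adjusted p = 6.93e-06, at 90.5 ± 12.8 CPM. PIM1 changed by 2.06 ± 0.0972, adjusted p = 8.17e-08, from 125 ± 0.975 CPM to 524 ± 13.8 CPM, a rise that kept its sign under every scaling. MYC (0.68 ± 0.0907, adjusted p = 6.46e-05), BCL6 (0.54 ± 0.101, adjusted p = 0.000747) and BCL2L1 (0.76 ± 0.109, adjusted p = 0.000111) rose, with signs that turned under mitochondrial and ribosomal protein scaling. IRF4 (-0.96 ± 0.231, adjusted p = 0.00393), JUNB (-0.69 ± 0.12, adjusted p = 0.000454), IER2 (-0.58 ± 0.125, adjusted p = 0.00192), CDK9 (-0.82 ± 0.105, adjusted p = 5.08e-05) and HEXIM1 (-0.92 ± 0.144, adjusted p = 0.000225) were lower. CCNT1 (0.10), NFKBIA (-0.19), CDKN1A (-0.03), BCL2A1 (-0.17), BCL2 (-0.08), EGR1 (0.54), FOS (0.29), POLR2A (0.13) and CCND2 (-0.01) did not pass. The largest losses included B3GNT2 (-4.66 ± 0.242, adjusted p = 1.22e-07), CMTR2 (-4.47 ± 0.238), DOLPP1 (-4.38 ± 0.25), the TFIID subunit TAF5 (-4.33 ± 0.28) and ARID5B (-4.21 ± 0.377). The largest gains were GH1 (8.16 ± 0.339, adjusted p = 6.18e-08), APOE (7.49 ± 0.307), PRR18 (6.90 ± 0.391), the nicotinic receptor CHRNA9 (6.74 ± 0.258), PYGM (6.24 ± 0.351) and TSPOAP1 (5.80 ± 0.195), the last at 144 ± 4.85 CPM against 2.58 ± 0.39 CPM.

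Mitotic genes fell in OCI-LY3 at 6 h (4 rose, 22 fell and 6 did not pass, or 4 and 23 adjusted over the list alone; adjusted p = 0.00138, or p = 0.44 with an estimated correlation). KIF11 (-1.76 ± 0.104), KIF2C (-1.49 ± 0.093), PLK4 (-2.38 ± 0.149) and TTK (-3.03 ± 0.2) were lower, while BIRC5, FOXM1, PTTG1 and PRC1 rose. Homologous-recombination genes, which repair DNA breaks, fell too (4 rose, 17 fell and 7 did not pass; adjusted p = 0.033, or p = 0.517 with an estimated correlation). FANCE (-2.58 ± 0.168), BARD1 (-2.53 ± 0.196) and RAD54L (-1.68 ± 0.139) led, against MRE11, FANCI, FANCD2 and FANCA. Nucleolar MYC targets fell (4 rose, 23 fell and 7 did not pass; adjusted p = 0.00293, or p = 0.582 with an estimated correlation), with GRWD1 (-3.33 ± 0.199) lower and NOP58, FBL, NPM1 and BOP1 higher. Immediate-early genes (1 rose, 12 fell and 15 did not pass; adjusted p = 0.134) and NF-kB targets (7 rose, 20 fell and 12 did not pass; adjusted p = 0.173) no longer passed as lists. Of the STAT3 and IL10 axis 4 rose, 6 fell and 6 did not pass, with a median of -0.46 that turned to 0.03 with upper-quartile scaling (adjusted p = 0.975). MHC class II genes, which present antigen and start very low in this line, rose (9 rose, 1 fell and 3 did not pass, or 10 and 1 adjusted over the list alone; adjusted p = 0.0291, or p = 0.517 with an estimated correlation). Their median turned to -0.63 with mitochondrial scaling; CD74 (1.03 ± 0.112) and HLA-DPA1 (0.95 ± 0.119) rose and HLA-DMB (-1.03 ± 0.226) fell. Histones (18 rose, 0 fell and 16 did not pass, or 17 and 0 adjusted over the list alone; adjusted p = 0.00534, or p = 0.517 with an estimated correlation) and ribosomal protein genes (74 rose, 0 fell and 1 did not pass; adjusted p = 2.69e-16, or p = 0.517 with an estimated correlation) rose, with medians of -0.42 and -0.41 under mitochondrial scaling.

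**Figure D3:**
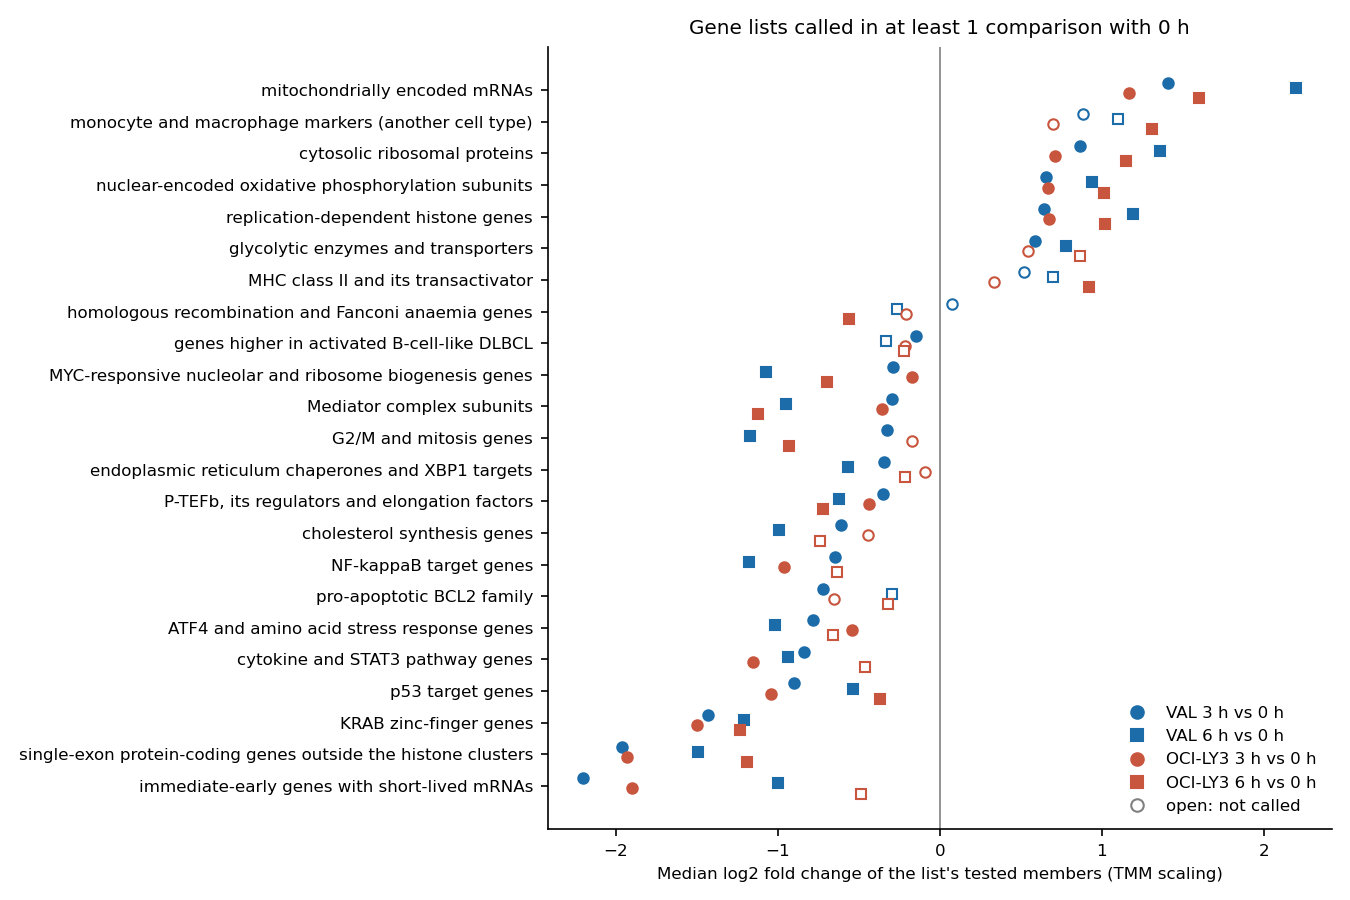
Median log2 fold change (x axis, default scaling) of the 23 gene lists called in at least 1 of the 4 comparisons with 0 h (y axis), circles for 3 h and squares for 6 h, filled where the list was called, with VAL in blue and OCI-LY3 in red. Immediate-early genes lay at -2.2 in VAL and -1.9 in OCI-LY3 at 3 h; lists to the right of 0, such as ribosomal proteins, moved left of 0 with mitochondrial scaling unless mitochondrially encoded.

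The lines shared more losses and gains than expected by chance. MCL1, JUNB, IRF4 and ID3 were lost in each, and GH1 and PHLDA1 were gained. At 3 h 2950 genes fell in both lines against 1000.3 expected if the lines were independent, and 2277 rose in both against 862 expected. The shared falls were 71.7% of those in VAL and 74.1% of those in OCI-LY3, and the shared rises 47% and 78.1%. The shared rises at 3 h were 1321 and 1328 without VAL 0 h replicate 1 or 2, 1145 and 1236 without OCI-LY3 0 h replicate 1 or 2, and 1256 and 1469 without OCI-LY3 3 h replicate 1 or 2. At 6 h the shared losses were 3891 against 1759 expected and the shared gains 3385 against 1565 expected. Genes called in opposite directions in the lines, either way round, numbered 79 at 3 h against 1909.9 expected, and 406 at 6 h against 3339 expected. The log2 changes correlated between lines with r = 0.666 at 3 h and 0.711 at 6 h (Spearman 0.681 and 0.71), over genes that are not independent replicates. Within a line, changes at 3 h and 6 h share the 0 h libraries, so part of their correlation is built in. It was 0.905 in VAL against 0.463 ± 0.0077 (SD of 100 draws) simulated for groups without any change, and 0.851 in OCI-LY3 against 0.455 ± 0.0072. The covariance was 0.897 in VAL against 0.0171 simulated, and 0.651 in OCI-LY3 against 0.0155. The part of the covariance built in by shared libraries was therefore small.

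**Figure D4:**
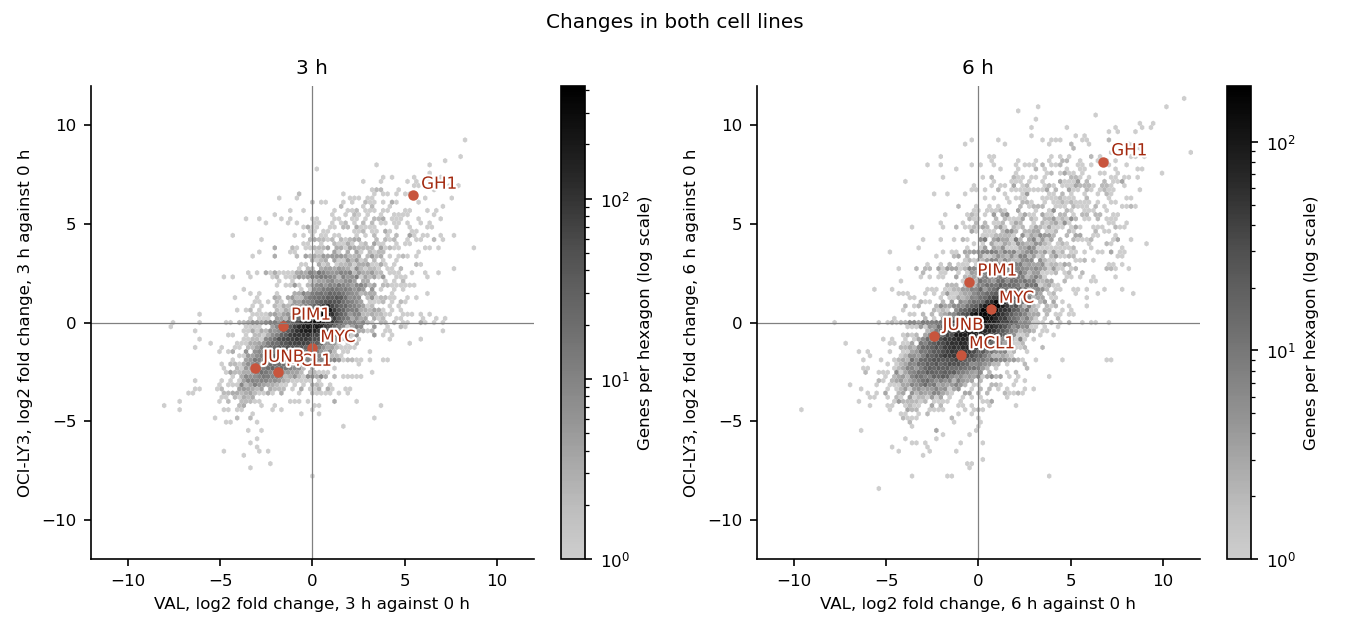
Log2 fold change against 0 h in VAL (x axis) and OCI-LY3 (y axis) at 3 h and 6 h, each hexagon shaded by its number of genes on a log scale, with MCL1, MYC, PIM1, JUNB and GH1 named. The changes correlated with r = 0.666 at 3 h and 0.711 at 6 h.

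Whether transcripts came back between 3 h and 6 h was asked within each line, where time in the inhibitor is the only labelled difference. CDKN1A, PIM1, BCL6, MCL1, NFKBIA and MYC rose in both lines. With mitochondrial scaling only CDKN1A of these still passed in VAL (BCL6 0.22, MCL1 0.18, MYC -0.08), and MCL1 did not in OCI-LY3. CDK9 stayed flat. In VAL 1235 genes rose, 2502 fell and 12637 did not pass between these times, and 692 and 667 changed at least 2-fold. CDKN1A rose by 2.30 ± 0.175, adjusted p = 3.7e-05, PIM1 by 1.10 ± 0.0965, adjusted p = 6.12e-05, BCL6 by 0.98 ± 0.102, adjusted p = 0.000136, MCL1 by 0.93 ± 0.157, adjusted p = 0.00175, NFKBIA by 1.28 ± 0.201, adjusted p = 0.00114 and MYC by 0.69 ± 0.0912, adjusted p = 0.000458. CCNT1 (0.91 ± 0.167, adjusted p = 0.00281) and IRF4 (0.83 ± 0.199, adjusted p = 0.0121) recovered in part, and CDK9 did not pass (-0.01 ± 0.106, adjusted p = 0.971). The highest rises were GPR157 (3.72 ± 0.28), HHEX (2.94 ± 0.302), PRELP (2.68 ± 0.168), the apoptosis inducer BBC3 (2.65 ± 0.234), to 100.1 ± 36.2 CPM from 16 ± 3.77 CPM, and CPM (2.61 ± 0.294). The largest falls were TTK (-2.73 ± 0.224), GCLC (-2.51 ± 0.175), PBDC1 (-2.40 ± 0.338), HSPA8 (-2.37 ± 0.204) and ARHGEF39 (-2.37 ± 0.206). Mitotic genes fell (0 rose, 22 fell and 10 did not pass, or 1 and 26 adjusted over the list alone; adjusted p = 3.21e-20, or p = 0.0329 with an estimated correlation), with BUB1 (-1.38 ± 0.0967), KIF11 (-1.26 ± 0.103) and CCNB2 (-1.54 ± 0.128) next to TTK. Immediate-early genes rose (13 rose, 0 fell and 15 did not pass, or 14 and 0 adjusted over the list alone; adjusted p = 1.54e-07, or p = 0.0329 with an estimated correlation), with ZFP36L1 (1.83 ± 0.153) and DUSP2 (1.26 ± 0.164). P53 targets rose (12 rose, 3 fell and 13 did not pass, or 14 and 4 adjusted over the list alone; adjusted p = 4.07e-06, or p = 0.305 with an estimated correlation), GADD45A (1.98 ± 0.18) and AEN (1.42 ± 0.185) with CDKN1A, against TIGAR, TNFRSF10B and DDB2, though their median turned negative with mitochondrial scaling. Heat-shock genes fell (0 rose, 6 fell and 11 did not pass, or 1 and 7 adjusted over the list alone; adjusted p = 0.009, or p = 0.58 with an estimated correlation), DNAJA1 (-2.36 ± 0.192) with HSPA8. The number of falls was 1630 without either VAL 0 h library and 1658 or 1661 without OCI-LY3 0 h replicate 1 or 2.

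In OCI-LY3 1958 genes rose, 2670 fell and 11746 did not pass from 3 h to 6 h, and 1260 and 770 changed at least 2-fold. PIM1 rose by 2.24 ± 0.098, adjusted p = 2.76e-06, MYC by 1.98 ± 0.0939, adjusted p = 3.15e-06, BCL6 by 1.80 ± 0.105, adjusted p = 7.4e-06, CDKN1A by 1.70 ± 0.175, adjusted p = 8.52e-05, JUNB by 1.61 ± 0.126, adjusted p = 2.58e-05, BCL2L1 by 1.21 ± 0.11, adjusted p = 4.96e-05 and MCL1 by 0.88 ± 0.158, adjusted p = 0.00197, while CDK9 did not pass (0.15 ± 0.105, adjusted p = 0.335). The stress gene GADD45B (3.14 ± 0.184), CHRNA9 (3.41 ± 0.2), ASTL (2.86 ± 0.229), TSPOAP1 (2.84 ± 0.166) and ID2 (2.60 ± 0.242) rose most. TAF5 (-2.53 ± 0.289), the DNA methyltransferase DNMT3B (-2.44 ± 0.325), CCDC102A (-2.33 ± 0.214) and KNSTRN (-2.23 ± 0.205) were among the largest falls. The STAT3 and IL10 axis rose (8 rose, 0 fell and 8 did not pass; adjusted p = 6.51e-12, or p = 0.0451 with an estimated correlation). Immediate-early genes did as well (13 rose, 0 fell and 15 did not pass, or 14 and 0 adjusted over the list alone; adjusted p = 9.05e-08, or p = 0.0451 with an estimated correlation), with IER5 (1.82 ± 0.129) and BTG2 (1.84 ± 0.155). NF-kB targets rose (17 rose, 5 fell and 17 did not pass, or 17 and 6 adjusted over the list alone; adjusted p = 7.42e-06, or p = 0.109 with an estimated correlation), led by BCL3 (2.12 ± 0.115) and TNFSF9 (2.03 ± 0.162), against NFKB2, CD40, NFKB1, CXCL10 and LTB. Mitotic genes fell (0 rose, 17 fell and 15 did not pass, or 0 and 19 adjusted over the list alone; adjusted p = 5.68e-06, or p = 0.152 with an estimated correlation). Of the 4112 genes lower at 3 h in VAL 312 (7.59%) rose again and 1357 fell further. Of 3983 in OCI-LY3 501 (12.6%) rose again and 1561 fell further. Over all 16374 tested genes 1235 rose and 2502 fell in VAL, and 1958 and 2670 in OCI-LY3. Rising again was therefore about as frequent among the lost genes as among all genes, while falling further was more frequent. These shares move with the calls: in VAL 511 genes rose and 771 fell with that line alone, and 356 and 7672 with mitochondrial scaling; in OCI-LY3 3749 and 4072, and 973 and 3922. Of the 2950 genes lower at 3 h in both lines 270 rose again in VAL and 432 in OCI-LY3, and 187 did so in both against 39.5 expected, among them CD69, BBC3, SLC30A1 and ZNF14. The number of rises in OCI-LY3 went from 1070 without OCI-LY3 6 h replicate 1, through 1076, 1215 and 1239 without 3 h replicate 2, 3 h replicate 1 and 6 h replicate 2, to 3841 without the VAL 3 h and 6 h libraries numbered 1. Falls were 1538 without 3 h replicate 2, 1549 without 6 h replicate 2 and 1559 without 6 h replicate 1.

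The untreated lines were compared to show where each started; line and sequencing lane are the same split, so a lane effect cannot be told apart from a line effect. Line names were taken from the labels, and the identity of the lines was not tested. OCI-LY3 had less BCL2, IRF4 and MHC class II, with more MYC and BCL2A1. MCL1 and CDK9 did not pass. In OCI-LY3 4880 genes were higher, 4332 lower and 7162 did not pass, with 2499 and 2974 at least 2-fold apart. BCL2 differed by -4.22 ± 0.463, adjusted p = 1.58e-05, at 23.1 CPM against 430 CPM. IRF4 differed by -3.31 ± 0.188, adjusted p = 9.18e-08, MYC by 0.94 ± 0.0912, adjusted p = 6.03e-06, BCL2A1 by 1.01 ± 0.144, adjusted p = 0.000114 and BCL2L1 by 0.66 ± 0.109, adjusted p = 0.000334. MCL1 (0.24 ± 0.154, adjusted p = 0.218) and CDK9 (-0.06 ± 0.103, adjusted p = 0.677) did not pass. Several genes had no count in the other line, so least folds are given. PLEKHA5 was at least 1890-fold higher in OCI-LY3, NPTN at least 1080-fold, MID1IP1 at least 934-fold, NMU at least 695-fold and SHROOM3 at least 346-fold. The chaperone HSPB1 was at least 8540-fold lower in OCI-LY3, HMGN3 at least 2160-fold, PFN2 at least 1970-fold, GYPC at least 1950-fold and GAMT at least 1800-fold. These floors cover counting error only. MHC class II genes were lower in OCI-LY3 (1 higher, 11 lower, 1 not passing, or 2 and 11 adjusted over the list alone; adjusted p = 3.06e-15, or p = 0.144 with an estimated correlation). HLA-DRA (-8.84 ± 0.296) and HLA-DRB1 (-7.20 ± 0.198) were lower and HLA-DOB (1.65 ± 0.252) higher. Interferon-stimulated genes were mixed (6 higher, 12 lower, 7 not passing; adjusted p = 0.0326, or p = 0.855 with an estimated correlation), with MX1 (-11.11 ± 0.417) and IFITM1 (-11.38 ± 0.46) lower and IFIT3, IFIT2, DDX58, OASL, IFI35 and ISG15 higher. The count of genes higher in OCI-LY3 was 2973 and 2985 without VAL 0 h replicate 1 or 2, and 3161 and 3055 without OCI-LY3 0 h replicate 1 or 2.

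Whether the lines responded differently was tested as the change in OCI-LY3 minus that in VAL. At 6 h the lists of NF-kB targets, the STAT3 and IL10 axis and chaperones differed upward in OCI-LY3, and none did with an estimated correlation. With the default scaling MYC and BCL6 fell at 3 h in OCI-LY3 and did not pass in VAL. With mitochondrial scaling they fell in VAL too (-1.44 and -1.28), and their differences between lines, at -1.0 and -1.09 with wider errors, did not pass (adjusted p = 0.279 and 0.209). At 3 h 447 genes differed upward, 541 downward and 15386 did not pass. Leaving out any library moved these counts over 1.5-fold, except VAL 3 h replicate 1 for the upward count, from 34 downward without VAL 0 h replicate 1 to 2302 without VAL 3 h replicate 2, and from 94 upward without OCI-LY3 3 h replicate 1 to 1440 without VAL 3 h replicate 2. At 3 h MYC differed by -1.28 ± 0.129, adjusted p = 0.00106, BCL6 by -1.40 ± 0.144, adjusted p = 0.00108, PIM1 by 1.44 ± 0.134, adjusted p = 0.000802, NFKBIA by 2.08 ± 0.257, adjusted p = 0.00248 and IRF4 by 1.35 ± 0.321, adjusted p = 0.0364. JUNB (0.82 ± 0.182, adjusted p = 0.0303) and IER2 (0.99 ± 0.185, adjusted p = 0.0159) were lost less in OCI-LY3. MCL1 (-0.63 ± 0.22, adjusted p = 0.11) did not pass, so its larger loss in OCI-LY3 at 3 h is not shown to differ. The widest upward differences at 3 h included LAX1 (5.43 ± 0.686), PHLDA3 (4.05 ± 1.05), KIF1BP (3.29 ± 0.36) and RGS2 (3.24 ± 0.619). The widest downward were PLEKHA5 (-6.84 ± 1.65), FCRL4 (-4.89 ± 1.19), UST (-3.70 ± 0.456), SPON2 (-3.60 ± 0.798) and NMNAT3 (-3.35 ± 0.769). LAX1, PHLDA3, RGS2 and SPON2 stood at 0.0182 to 0.366 CPM in OCI-LY3, so their changes there rest on few counts. PLEKHA5 and FCRL4 had no count in untreated VAL and rose there at least 6.32-fold and 2.92-fold on 13 and 6 counts. VAL 3 h replicate 2 held 1.75% of the OCI-LY3 level of genes at or near 0 in untreated VAL, so these differences are in doubt.

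At 6 h 2021 genes differed upward, 2362 downward and 11991 did not pass, with 1264 and 1471 at least 2-fold. PIM1 (2.57 ± 0.135, adjusted p = 4.22e-06), NFKBIA (2.11 ± 0.248, adjusted p = 0.000366), JUNB (1.70 ± 0.178, adjusted p = 0.000202), IER2 (1.47 ± 0.182, adjusted p = 0.000471), IRF4 (1.38 ± 0.299, adjusted p = 0.00738) and BCL2L1 (1.37 ± 0.155, adjusted p = 0.000309) stood higher in the response of OCI-LY3. MCL1 (-0.67 ± 0.22, adjusted p = 0.0439), BCL6 (-0.58 ± 0.143, adjusted p = 0.0135) and CDKN1A (-1.06 ± 0.236, adjusted p = 0.00835) stood lower, but with mitochondrial scaling they differed by -0.04, 0.04 and -0.46 and did not pass. The widest upward differences were in genes without a count in untreated OCI-LY3. There HHEX rose at least 72.1-fold, TBKBP1 at least 60.9-fold, ABHD10 at least 6.62-fold, RAB4A at least 5.95-fold and RNF2 at least 3.31-fold. ABHD10, RAB4A and RNF2, expressed in VAL, rose on 10, 9 and 5 counts and are in doubt. The widest downward were DTX4 (-4.46 ± 0.183), the DNA demethylase TET2 (-3.98 ± 0.788), E2F7 (-3.87 ± 0.377), UST (-3.51 ± 0.488) and IGF2BP3 (-3.45 ± 0.526). NF-kB targets differed upward (15 higher, 2 lower, 22 not passing; adjusted p = 7.71e-05, or p = 0.279 with an estimated correlation), with BCL3 (3.13 ± 0.155, adjusted p = 4.22e-06), RELB (2.19 ± 0.187) and ICAM1 (2.56 ± 0.222), against TRAF1 and LTA. So did the STAT3 and IL10 axis (6 higher, 2 lower, 8 not passing; adjusted p = 2.71e-05, or p = 0.279 with an estimated correlation), with SOCS1 (2.14 ± 0.26), against JAK1 and STAT3. Mitotic genes (12 higher, 1 lower, 19 not passing; adjusted p = 6.6e-05, or p = 0.35 with an estimated correlation) fell less in OCI-LY3, BUB1 (1.34 ± 0.135) and CCNB2 (1.47 ± 0.177) included, against KIF2C. Folding genes of the endoplasmic reticulum (11 higher, 1 lower, 8 not passing; adjusted p = 2.71e-05, or p = 0.429 with an estimated correlation) did so too, with CALR (2.44 ± 0.299), XBP1 (2.99 ± 0.421) and HSPA5 (1.91 ± 0.283) against EDEM1. Heat-shock genes (6 higher, 1 lower, 10 not passing; adjusted p = 0.000437, or p = 0.778 with an estimated correlation) included DNAJB1 (2.11 ± 0.209) and DNAJA1 (2.37 ± 0.26), against BAG3 (-1.86 ± 0.258). Homologous-recombination genes differed downward (2 higher, 9 lower, 17 not passing; adjusted p = 0.0177, or p = 0.778 with an estimated correlation), BARD1 (-2.14 ± 0.263) first, against RAD51C and FANCF, and their median turned sign with mitochondrial scaling. Downward counts were 1034 and 1094 without VAL 0 h replicate 1 or 2, 1096 and 1129 without OCI-LY3 0 h replicate 1 or 2, and 1453 and 1350 without OCI-LY3 6 h replicate 1 or 2. Upward counts were 1235 and 1347 without OCI-LY3 6 h replicate 1 or 2.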

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

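The per-line tests of the low-level risers, the test of the resubmitted libraries and the tests of induction for the trace of OCI-LY3 genes were chosen only after the results were seen; the other tests were stated before.

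Some of the core genes responded differently in the lines at 3 h. Each gene here is listed because a direct test of the difference, OCI-LY3 change minus VAL change, passed. MYC differed by -1.28 (standard error 0.129, adjusted p = 0.00106), as it fell in OCI-LY3 (-1.30) and did not pass in VAL (-0.02). BCL6 differed by -1.40 (adjusted p = 0.00108), with changes of -1.26 and 0.14. PIM1 differed by 1.44 (adjusted p = 0.000802), as it fell in VAL and did not pass in OCI-LY3. NFKBIA differed by 2.08 (adjusted p = 0.00248), IRF4 by 1.35 (adjusted p = 0.0364), IER2 by 0.99 (adjusted p = 0.0159) and JUNB by 0.82 (adjusted p = 0.0303), all having fallen less in OCI-LY3. With mitochondrial scaling the differences of MYC (-1.0), BCL6 (-1.09), JUNB (1.14) and IER2 were of similar size or larger, with wider errors, and did not pass.

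At 6 h PIM1 differed by 2.57 (adjusted p = 4.22e-06), NFKBIA by 2.11 (adjusted p = 0.000366), JUNB by 1.70 (adjusted p = 0.000202), IER2 by 1.47 (adjusted p = 0.000471), IRF4 by 1.38 (adjusted p = 0.00738) and BCL2L1 by 1.37 (adjusted p = 0.000309). CDKN1A differed by -1.06 (adjusted p = 0.00835), MCL1 by -0.67 (adjusted p = 0.0439) and BCL6 by -0.58 (adjusted p = 0.0135). Each of these differences passed, but with mitochondrial scaling CDKN1A (-0.46), MCL1 (-0.04) and BCL6 (0.04) did not pass.

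Among the widest differences at 3 h, LAX1, an adaptor of lymphocyte signalling, changed by 2.51 in OCI-LY3 (0.0461 to 0.285 CPM) and -2.93 in VAL, a difference of 5.43 (adjusted p = 0.00282). PHLDA3 differed by 4.05 (adjusted p = 0.0488), with changes of 0.77 and -3.27, KIF1BP by 3.29 (adjusted p = 0.00143) and RGS2 by 3.24 (adjusted p = 0.0174). KIF1BP starts at 68988721 on chromosome 10, after the end of DDX21 at 68985073 on the same strand. DDX21 stood at 834.6 CPM in untreated OCI-LY3, and reads running on from it into KIF1BP were not tested for. SPON2 differed by -3.60 (adjusted p = 0.0297). LAX1, PHLDA3, RGS2 and SPON2 stood at 0.0182 to 0.366 CPM in OCI-LY3, so opposite regulation is not shown. PLEKHA5 differed by -6.84 (adjusted p = 0.0462), FCRL4 by -4.89 (adjusted p = 0.043), UST by -3.70 (adjusted p = 0.00248) and NMNAT3 by -3.35 (adjusted p = 0.0331). These last 4 are near 0 in VAL; without VAL 3 h replicate 2 the values were -4.16, -4.22, -3.29 and -2.64, and only UST passed.

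At 6 h genes with no count in untreated OCI-LY3 rose there: HHEX, a difference of 8.17 (adjusted p = 0.000676), TBKBP1, 7.66 (adjusted p = 0.000217), ABHD10, 7.04 (adjusted p = 0.000499), RNF2, 6.86 (adjusted p = 0.00455), and RAB4A, 5.91 (adjusted p = 0.00896). These fitted values depend on the prior count and are no bounds. ABHD10, RNF2 and RAB4A, on 10, 5 and 9 counts, are in doubt. VAL genes at or near 0 in untreated OCI-LY3 held 0.477% and 0.185% of their VAL level in its 6 h replicates 1 and 2. These include ABHD10, RAB4A and TBKBP1, so this is no separate check. Others of lower level held 2.26% and 1.8% in sum, led by genes at up to 98.7% and 96%. Their median shares were 0.719% and 0.139%. DTX4 differed by -4.46 (adjusted p = 1.34e-06), but its rise of 2.03 in VAL may not hold with mitochondrial scaling. TET2 differed by -3.98 (adjusted p = 0.00475), E2F7 by -3.87 (adjusted p = 0.000174), UST by -3.51 (adjusted p = 0.000823) and IGF2BP3 by -3.45 (adjusted p = 0.00128); UST reached only 0.412 CPM in VAL.

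Genes under 2 CPM at 0 h that rose over 4-fold, GH1, APOE, CHRNA9 and MPO among them, numbered 607 and 1241 in VAL and 542 and 1286 in OCI-LY3 at 3 h and 6 h. Failure to end transcription after CDK9 loss is a candidate explanation, since polymerase would then run from an upstream gene into its neighbour. For an upstream expressed neighbour the ratio of shares, risers over other genes, was 0.989 and 1.21 in VAL at 3 h and 6 h. In OCI-LY3 it was 1.49 and 1.61 (Fisher's exact test p = 0.000174 and 1.77e-09), and 0.86 and 1.06 for downstream neighbours. The smallest, 0.989, was the test, so upstream neighbours were not more frequent in every comparison. Only neighbours within 10 kb and of at least 20 CPM at 0 h were counted. Farther or less expressed genes were not covered, so the test cannot decide on read-through. Read-in from a convergent gene, with a smallest ratio of 1.32, and scaling, with 40.9% of risers still called under mitochondrial scaling, stay open. Split by line after that result was seen, VAL gave 0.989, 1.32 and 40.9, and OCI-LY3 gave 1.49, 1.45 and 72%, so scaling is argued against in OCI-LY3 alone and read-through and read-in cannot be told apart from induction there.

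The treated VAL replicates differed more than any other pair, and their differences at 3 h and 6 h were correlated (r = 0.436), unlike those of other pairs within a line (-0.0443 to 0.0512). A trend with transcript length is argued against as the whole cause, because the correlation went from 0.437 to 0.404 after its removal. Resubmission of the libraries numbered 1 is argued against by the VAL 0 h pair, whose library numbered 1 was resubmitted too and which had a chi-square per degree of freedom of 1.66. A stronger response in one library of the pair stays open, with correlations to the OCI-LY3 change of 0.0367 at 3 h and 0.18 at 6 h.

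VAL 3 h replicate 2 held genes of OCI-LY3 that had at most 3 counts in each untreated VAL library, such as VIM, NMU and PLEKHA5. The 13 of high level summed to 1.66% of their OCI-LY3 level, against 0.155% in replicate 1. A trace of OCI-LY3 RNA or reads is consistent with 30 other genes of lower level, which held 1.75% there and 0.489% in replicate 1. Induction by the inhibitor is argued against for most of these 30, as their median share was 1.39% in replicate 2 and 0% in replicate 1 (26 higher in replicate 2), and stays open for the few that carry the summed lower-level ratio of 0.279. Differences between lines at 3 h that rest on genes near 0 in VAL are therefore uncertain, while genes such as MCL1, at comparable levels in both lines, would move little with such a share.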

How the results depend on the processing

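Of the 17 alternatives the 4 listed above as added were chosen only after the data were seen. The losses of MCL1, JUNB, IRF4 and NFKBIA at 3 h kept their direction under every alternative tried, while how many genes rose depends on scaling. Of 375 named changes 374 kept direction and side of the threshold with limma-voom, 368 with DESeq2's size factors, 366 with DESeq2's Wald test and 264 with mitochondrial scaling. With any of the 12 libraries left out 56 lost their call, 8 gained one and 0 reversed. A library left alone in its group was assumed to vary like the other groups. Limma on the deposited table was run without adding 1, because that table is already log2. Causes were not tested, except that scalings move all genes by construction and that fewer genes or libraries were used where stated.

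With DESeq2's size factors genes lower numbered 316 (line difference at 3 h). With no composition factor genes higher numbered 2194 (VAL 3 h), 3151 (VAL 6 h), 1786 (OCI-LY3 3 h), 3028 (OCI-LY3 6 h), 773 (line difference at 3 h), 1054 (both lines at 3 h) and 1857 (both lines at 6 h) and genes lower numbered 121 (line difference at 3 h) and 1458 (line difference at 6 h). With upper-quartile factors genes higher numbered 5303 (OCI-LY3 3 h), 7027 (OCI-LY3 6 h), 2314 (VAL 6 h over 3 h), 3391 (OCI-LY3 6 h over 3 h), 3905 (both lines at 3 h) and 5242 (both lines at 6 h) and genes lower numbered 3506 (OCI-LY3 6 h), 1485 (VAL 6 h over 3 h), 1590 (OCI-LY3 6 h over 3 h), 307 (line difference at 3 h) and 2468 (both lines at 6 h). Scaled to mitochondrially encoded mRNAs genes higher numbered 358 (VAL 3 h), 528 (VAL 6 h), 417 (OCI-LY3 3 h), 1008 (OCI-LY3 6 h), 356 (VAL 6 h over 3 h), 973 (OCI-LY3 6 h over 3 h), 1957 (untreated lines), 161 (both lines at 3 h) and 384 (both lines at 6 h) and genes lower numbered 11611 (VAL 3 h), 13516 (VAL 6 h), 10819 (OCI-LY3 3 h), 11775 (OCI-LY3 6 h), 7672 (VAL 6 h over 3 h), 123 (line difference at 3 h), 396 (line difference at 6 h), 9559 (both lines at 3 h) and 11144 (both lines at 6 h). Scaled to ribosomal protein mRNAs genes higher numbered 503 (VAL 3 h), 852 (VAL 6 h), 559 (OCI-LY3 3 h), 1174 (OCI-LY3 6 h), 425 (VAL 6 h over 3 h), 924 (OCI-LY3 6 h over 3 h), 253 (both lines at 3 h) and 559 (both lines at 6 h) and genes lower numbered 8130 (VAL 3 h), 10445 (VAL 6 h), 7956 (OCI-LY3 3 h), 10339 (OCI-LY3 6 h), 5459 (VAL 6 h over 3 h), 4972 (OCI-LY3 6 h over 3 h), 35 (line difference at 3 h), 453 (line difference at 6 h), 6569 (both lines at 3 h) and 8906 (both lines at 6 h).

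Without a low-count filter genes higher and lower numbered 1197 and 971 (line difference at 3 h). With a mean of at least 5 CPM, where fewer genes were tested, genes higher numbered 2767 (VAL 3 h), 3257 (VAL 6 h), 2266 (untreated lines) and 810 (line difference at 3 h) and genes lower numbered 2622 (OCI-LY3 3 h), 3455 (OCI-LY3 6 h), 1608 (VAL 6 h over 3 h), 245 (line difference at 3 h) and 1562 (line difference at 6 h). By DESeq2's Wald test genes higher and lower numbered 1020 and 860 (line difference at 3 h). By limma on the deposited log2 table they numbered 733 and 345 (line difference at 3 h). With each line fitted alone, on fewer libraries, genes higher numbered 2540 (VAL 3 h), 511 (VAL 6 h over 3 h), 4520 (OCI-LY3 3 h) and 3749 (OCI-LY3 6 h over 3 h) and genes lower numbered 771 (VAL 6 h over 3 h) and 4072 (OCI-LY3 6 h over 3 h). With a replicate block genes higher and lower numbered 868 and 1498 (line difference at 3 h). With at least 2-fold required genes higher numbered 1943 (VAL 3 h), 3505 (VAL 6 h), 1088 (OCI-LY3 3 h), 2511 (OCI-LY3 6 h), 692 (VAL 6 h over 3 h), 1260 (OCI-LY3 6 h over 3 h), 2499 (untreated lines), 1264 (line difference at 6 h), 635 (both lines at 3 h) and 1739 (both lines at 6 h) and genes lower numbered 2608 (VAL 3 h), 2326 (OCI-LY3 3 h), 3573 (OCI-LY3 6 h), 667 (VAL 6 h over 3 h), 770 (OCI-LY3 6 h over 3 h), 285 (line difference at 3 h), 1471 (line difference at 6 h), 1591 (both lines at 3 h) and 2280 (both lines at 6 h). With one weight per group genes higher numbered 4515 (OCI-LY3 3 h), 245 (VAL 6 h over 3 h), 3264 (OCI-LY3 6 h over 3 h) and 843 (line difference at 3 h) and genes lower numbered 1054 (VAL 6 h over 3 h) and 1533 (line difference at 3 h). Without the treated VAL libraries numbered 1 genes higher numbered 4586 (OCI-LY3 3 h), 2352 (VAL 6 h over 3 h), 3841 (OCI-LY3 6 h over 3 h), 1176 (line difference at 3 h) and 3602 (both lines at 3 h) and genes lower numbered 4448 (OCI-LY3 6 h over 3 h) and 2533 (line difference at 3 h). Without the treated VAL libraries numbered 2 genes higher numbered 4579 (OCI-LY3 3 h), 3834 (OCI-LY3 6 h over 3 h), 2876 (line difference at 3 h) and 3903 (line difference at 6 h) and genes lower numbered 4445 (OCI-LY3 6 h over 3 h), 3797 (line difference at 3 h) and 4224 (line difference at 6 h). The labels pair no samples by number, so the replicate block was not used for the report.

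Leaving out each library in turn gave, from lowest to highest, 2244 to 5316 for genes higher in VAL 3 h (4840 with all libraries), 1491 to 3467 for genes higher in OCI-LY3 3 h (2917 with all libraries), 1630 to 2927 for genes lower in VAL 6 h over 3 h (2502 with all libraries), 1070 to 2474 for genes higher in OCI-LY3 6 h over 3 h (1958 with all libraries), 1538 to 3252 for genes lower in OCI-LY3 6 h over 3 h (2670 with all libraries), 2973 to 5338 for genes higher in untreated lines (4880 with all libraries), 94 to 1440 for genes higher in line difference at 3 h (447 with all libraries), 34 to 2302 for genes lower in line difference at 3 h (541 with all libraries), 1235 to 2706 for genes higher in line difference at 6 h (2021 with all libraries), 1034 to 3148 for genes lower in line difference at 6 h (2362 with all libraries) and 1145 to 2620 for genes higher in both lines at 3 h (2277 with all libraries). The libraries that moved a count over 1.5-fold are named with it in the report. Depth limits the low-count genes, which the minimum of 5 CPM leaves out.

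Lists called with an estimated correlation numbered 1 each in VAL 3 h and OCI-LY3 3 h. They numbered 2 each in VAL 6 h over 3 h and OCI-LY3 6 h over 3 h, and 0 elsewhere. With fry they numbered 29 (VAL 6 h), 30 (OCI-LY3 3 h), 27 (OCI-LY3 6 h), 21 (untreated lines) and 0 (line difference at 3 h), and with a replicate block 8 (line difference at 3 h).

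The correlation between lines at 3 h was 0.666, and 0.358 with no low-count filter, 0.777 with a mean of at least 5 CPM, 0.778 with the deposited log2 table and 0.789 with each line fitted alone. At 6 h it was 0.711, and 0.46 with no low-count filter and 0.787 with each line fitted alone. The correlation of 3 h and 6 h changes in VAL was 0.868, and 0.662 with no low-count filter and 0.759 with the treated VAL libraries numbered 1 left out, and 0.768 to 0.882 with a library left out. The correlation of 3 h and 6 h changes in OCI-LY3 was 0.826, and 0.832 with no composition factor, 0.818 with upper-quartile factors, 0.854 with mitochondrial scaling, 0.843 with ribosomal protein scaling, 0.62 with no low-count filter, 0.834 with a mean of at least 5 CPM, 0.837 with DESeq2's Wald test, 0.854 with limma-voom, 0.856 with the deposited log2 table, 0.874 with each line fitted alone, 0.854 with one weight per group and 0.858 with genes over 10 times higher in the other line left out, and 0.759 to 0.843 with a library left out. Here correlations within a line are of fitted changes, not of changes between mean CPM. Genes are not independent replicates.

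With no composition factor the log2 changes turned to MNAT1 -0.06, SUPT5H -0.02, SUPT6H 0.00 in VAL 3 h, and NPM1 -0.02 in VAL 6 h, and FOXM1 -0.06, NOP58 -0.13 in OCI-LY3 6 h. With upper-quartile factors BCL2A1 turned to 0.35 and CDKN1A to 0.49 in OCI-LY3 6 h. Scaled to mitochondrially encoded mRNAs the log2 changes turned to BCL6 -1.28, POLR2A -0.95, CCL17 -0.29, CCL22 -0.62, CD74 -0.59, EBI3 -0.29, FDXR -0.96, JAK1 -0.35, MNAT1 -1.11, MT-ND2 -0.02, NELFCD -0.92, RPL28 -0.42, SDHC -0.57, STAT3 -0.55, STAT5A -0.89, SUPT5H -1.06, SUPT6H -1.06, ZNF37A -1.01, ZNF69 -0.29, ZNF83 -0.56 in VAL 3 h, and MYC -1.51, BCL2 -1.87, BCL6 -1.06, FOS -1.29, POLR2A -1.86, CDKN1A -1.13, BBC3 -0.27, FBL -1.51, KLF6 -0.74, NPM1 -1.67, PRC1 -1.54 in VAL 6 h, and POLR2A -1.07, CCL17 -0.27, CCL22 -0.35, CD74 -0.50, EBI3 -0.41, FDXR -0.60, NELFCD -0.84, SUPT5H -0.81 in OCI-LY3 3 h, and MYC -0.87, CCNT1 -1.46, BCL2L1 -0.80, BCL6 -1.02, EGR1 -1.01, POLR2A -1.42, BIRC5 -1.04, BOP1 -1.03, CD74 -0.52, FANCA -0.84, FANCD2 -1.04, FANCI -1.09, FBL -0.73, FOXM1 -1.25, HLA-DPA1 -0.61, MRE11 -0.98, NOP58 -1.32, NPM1 -0.82, PRC1 -1.11, PTTG1 -0.89 in OCI-LY3 6 h, and MYC -0.08, VAV2 -0.40 in VAL 6 h over 3 h, and BCL6 0.04, EDEM1 0.05 in line difference at 6 h. Scaled to ribosomal protein mRNAs the log2 changes turned to BCL6 -0.69, POLR2A -0.33, CCL22 -0.06, CD74 -0.06, FDXR -0.46, MNAT1 -0.55, NELFCD -0.37, SDHC -0.03, STAT5A -0.34, SUPT5H -0.52, SUPT6H -0.50, ZNF37A -0.39 in VAL 3 h, and MYC -0.69, BCL6 -0.23, POLR2A -1.01, CDKN1A -0.37, FBL -0.76, NPM1 -0.90, PRC1 -0.72 in VAL 6 h, and CD74 -0.06, FDXR -0.17, NELFCD -0.40, SUPT5H -0.39 in OCI-LY3 3 h, and MYC -0.45, CCNT1 -1.03, BCL2L1 -0.37, BCL6 -0.59, POLR2A -1.0, BIRC5 -0.61, BOP1 -0.61, CD74 -0.10, FANCA -0.42, FANCD2 -0.62, FANCI -0.66, FBL -0.31, FOXM1 -0.82, HLA-DPA1 -0.18, MRE11 -0.56, NOP58 -0.89, NPM1 -0.39, PRC1 -0.68, PTTG1 -0.46 in OCI-LY3 6 h, and VAV2 -0.14 in VAL 6 h over 3 h. Without treated VAL libraries numbered 1 BCL2 turned to -0.36 in VAL 6 h, and without those numbered 2 to 0.25 in VAL 3 h.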

Other observations

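The test of gene span on returning genes was stated before its result was seen.

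Relative to the other genes of a library, genes of B-cell function went both ways. In VAL at 3 h B-cell identity genes went both ways (11 rose, 10 fell and 9 did not pass, or 11 and 11 adjusted over the list alone; adjusted p = 0.795), with a median of 0.11 and a mean of -0.30. B-cell receptor signalling genes did too (11 rose, 7 fell and 10 did not pass; adjusted p = 0.7), with a median of 0.14 and a mean of -0.04. With mitochondrial scaling the medians of both lists were -1.32 and -1.29, near -1.23 for all tested genes. From 3 h to 6 h the receptor signalling list fell in VAL (2 rose, 12 fell and 14 did not pass, or 3 and 14 adjusted over the list alone; adjusted p = 0.0036, or p = 0.224 with an estimated correlation) and in OCI-LY3 (2 rose, 12 fell and 14 did not pass, or 3 and 13 adjusted over the list alone; adjusted p = 0.0162, or p = 0.4 with an estimated correlation). BLNK (-1.19 ± 0.107) and LYN (-0.81 ± 0.0876) fell in VAL against BCL10 and VAV2. Germinal-centre markers in VAL at 3 h were balanced (6 rose, 6 fell and 6 did not pass, or 6 and 7 adjusted over the list alone; adjusted p = 0.469; median 0.02, mean -0.16). Markers of the activated B-cell type fell in VAL at 3 h (6 rose, 10 fell and 6 did not pass, or 7 and 10 adjusted over the list alone; adjusted p = 0.0282, or p = 0.159 with an estimated correlation), with a median that turned to 0.02 under upper-quartile scaling. MHC class II genes in VAL did not pass at 3 h (9 rose, 1 fell and 3 did not pass, or 9 and 2 adjusted over the list alone; adjusted p = 0.107).

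Targets of ATF4, the amino-acid stress factor, fell in VAL at 3 h (6 rose, 10 fell and 2 did not pass; adjusted p = 0.00031, or p = 0.235 with an estimated correlation) and in OCI-LY3 (3 rose, 9 fell and 6 did not pass; adjusted p = 0.00531, or p = 0.364 with an estimated correlation). Folding genes of the endoplasmic reticulum fell in VAL at 3 h (4 rose, 10 fell and 6 did not pass; adjusted p = 0.0416, or p = 0.595 with an estimated correlation) and did not pass in OCI-LY3 (4 rose, 5 fell and 11 did not pass, or 4 and 6 adjusted over the list alone; adjusted p = 0.314). Cholesterol synthesis fell in VAL at 3 h (3 rose, 12 fell and 6 did not pass; adjusted p = 0.0153, or p = 0.213 with an estimated correlation) and did not pass in OCI-LY3 (4 rose, 10 fell and 7 did not pass, or 4 and 11 adjusted over the list alone; adjusted p = 0.139). Glycolysis rose in VAL at 3 h (15 rose, 2 fell and 4 did not pass; adjusted p = 0.0451, or p = 0.628 with an estimated correlation), with a negative median under mitochondrial and ribosomal protein scaling. Mediator subunits fell in VAL at 6 h (6 rose, 20 fell and 6 did not pass, or 7 and 21 adjusted over the list alone; adjusted p = 0.0045, or p = 0.184 with an estimated correlation) and in OCI-LY3 (5 rose, 20 fell and 7 did not pass; adjusted p = 0.012, or p = 0.421 with an estimated correlation). Heat-shock genes did not pass in VAL at 3 h (6 rose, 5 fell and 6 did not pass; adjusted p = 0.439; median 0.29, mean -0.39).

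Several lists did not pass in VAL at 3 h. They were metabolic MYC targets (11 rose, 5 fell and 12 did not pass; adjusted p = 0.439), subunits of RNA polymerase II (5 rose, 1 fell and 5 did not pass; adjusted p = 0.372) and replication genes of G1 and S phase (8 rose, 15 fell and 7 did not pass; adjusted p = 0.115). Interferon-stimulated genes (11 rose, 2 fell and 12 did not pass; adjusted p = 0.264), autophagy genes (8 rose, 4 fell and 11 did not pass; adjusted p = 0.372) and splicing factors (10 rose, 9 fell and 7 did not pass, or 10 and 10 adjusted over the list alone; adjusted p = 0.996) did not either. Markers of T and NK cells did not pass in VAL at 3 h (1 rose, 1 fell and 5 did not pass, or 0 and 1 adjusted over the list alone; adjusted p = 0.806). Myeloid markers rose in OCI-LY3 at 6 h (3 rose, 0 fell and 2 did not pass; adjusted p = 0.0328, or p = 0.421 with an estimated correlation); MPO, at 0 counts in both untreated lines, and CD14 (4.94 ± 0.389) were among them.

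Genes such as GADD45A, JUN, CD69 and ID3 fell at 3 h and rose again by 6 h in both lines. Polymerase released again or late would reach the end of a short gene first, so by hypothesis returning genes should be short. The 179 protein-coding genes that returned spanned a median of 14.6 kb against 25.2 kb for 2466 other genes lower at 3 h in both lines. The ratio was 0.582, and a two-sided permutation test gave p = 1e-05, the smallest that 1e+05 resamples can give. The bound stated beforehand was a ratio under 0.5, which was missed, as was the bound of 0.8 against the idea. A short span may be part of why these genes returned. Of the 187 genes of any type 10 are on the immediate-early list.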
